A study of Mus musculus with 17 samples.

How the data were processed

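RNA of FOXA2-positive and FOXA2-negative mouse cells from 3 treatments was sequenced as SMART-Seq v2 libraries, per the labels. For each of 17 libraries the authors deposited a table of raw counts per Ensembl gene, not normalised. The submitters' processing notes name UMI-tools 1.0.0, cutadapt 1.18, HTSeq 0.11.2, DESeq2 1.26.0 and the build mm10, and the names of the deposited count tables record extraction of unique molecular identifiers, trimming and removal of duplicates by identifier. The aligner, the annotation release, the strand setting and how multi-mapping reads were treated before counting are not given in the sources used here. Since the strand setting is open, reads of a gene and of an overlapping antisense gene, such as Tbx3os1 beside Tbx3, cannot be told apart. Each table held 49671 genes and 5 summary lines, and 26831 genes had at least 1 count in the series. The summary lines, which name no gene, took between 49.3% and 54.4% of all tallied reads (no feature 30.4% to 35.0%, not unique 16.0% to 21.5%, ambiguous 0.4% to 0.52%) and stayed out of library sizes and tests. Symbols were found for 49326 genes and coordinates for 49412 in the GENCODE M21 annotation of GRCm38, the assembly also called mm10.

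Groups were taken from the library titles, as treatment and sorted fraction, with 3 libraries in 5 groups and 2 in FOXA2-positive LDN. The groups, tests, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined; the alternatives without both RA libraries numbered 1 and without genes of chromosomes 6, 8 and Y were chosen after seeing the data, as were the block within treatment for gene lists and a list of 2-cell-stage genes. Nothing states that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17813, libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation was fitted to the 6 groups with 11 residual degrees of freedom and a common biological coefficient of variation of 0.632. From this model came 9 pairwise comparisons and 3 interaction contrasts, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Every adjusted p for a gene is from edgeR's quasi-likelihood test. Levels are TMM-scaled CPM, given as mean ± SD over libraries, and log2 fold changes are edgeR estimates. Their standard errors (SE) were not given by edgeR's test. Each was calculated as the size of the log2 fold change divided by the square root of the F statistic. Such errors are approximate, above all where counts are low.

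Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with an exact 95% binomial counting interval. For correlations, principal components (of log2 CPM with a prior count of 2) and chromosome medians, genes with a mean of at least 20 CPM were used. In all, 32 gene lists marking neural and other cell identities, signalling pathways, adhesion and cell state were tested with camera in limma 3.58.1, at the preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. Some lists share members, so their calls are not independent. The BMP-SMAD target list shares Msx1 and Msx2 with the dorsal neural tube list, Gata3 with surface ectoderm, and Nog and Bmper with BMP antagonists. The genes named in a pairwise comparison were those with an adjusted p under 0.05, a mean of at least 5 CPM over both groups and no overlap between the groups' libraries, up to 10 with the largest positive and 10 with the largest negative log2 fold change. Chance alone separates 10% of genes in this way for 3 against 3 libraries and 20% for 3 against 2. Predicted or unnamed genes were left out there. For interactions the rule took up to 10 genes with the smallest p, and Foxa2, Shh, Id1 and members of the gene lists could be named everywhere. Genes named outside this rule, because a count was small, because they were called in all 3 treatments or because they lie on the Y chromosome, were chosen after their values were seen. Some genes that passed these rules are counted but not reported by name here.

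Alternatives were DESeq2 1.42.0 with its own size factors, RLE scaling, no filter on low counts, a stricter filter of 5 CPM in 2 libraries, models of the compared groups alone, the replicate number as a block, and each library left out in turn. Whether replicate numbers pair the libraries was checked by the correlation, over 6669 genes, of deviations from the group means. In RA the FOXA2-positive and FOXA2-negative libraries of the same number correlated at 0.587, 0.238 and 0.277, each over the limit of 0.1 set for pairing, so the numbers were taken to pair the libraries there, from the data and not from a statement in the labels. Only number 1 stands apart: between libraries numbered 2 and 3 different numbers correlated at 0.243 and 0.168, about as high as the same numbers. These correlations therefore do not show that numbers 2 and 3 pair the libraries.

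The procedure was tested on simulated data. Of 20 simulations without any effect, the highest number of genes called in a contrast was 2. With 50 genes changed at each size in a simulated RA sort comparison (16823 genes), 12 of the 2-fold, 23 of the 4-fold, 25 of the 8-fold and 39 of the 16-fold changes were recovered, with 5 false calls among 104. Above 20 CPM the recovery was 12 of 20, 13 of 13, 17 of 17 and 23 of 24. For the simulated interaction of BMP4 against LDN (16811 genes) it was 5, 14, 15 and 24 of 50, with 0 false calls among 58. A simulated comparison of LDN with RA in FOXA2-positive cells gave 2 false calls among 85. In the simulated comparison of BMP4 with RA in FOXA2-negative cells there were 12 false calls among 105. That is a larger share than the threshold on adjusted p aims at, so false calls were not held to it in every comparison. Among 31 simulated lists of 12 genes in BMP4 against RA, the 2-fold list was found and none of the 30 unchanged lists was called. The simulated genes varied independently, so this does not test the preset correlation for genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.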

Results

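RNA was measured in 17 libraries from R1 mouse embryonic stem cells that carry a FOXA2-Venus reporter, in a series on how neural tube organoids form a floor plate. FOXA2 is the forkhead transcription factor that marks the floor plate, the ventral midline of the neural tube, and each treatment was represented by FOXA2-positive and FOXA2-negative cells. Cells of the RA groups had 18 hours of retinoic acid, a vitamin A derivative that patterns the posterior nervous system. The BMP4 and LDN groups had 18 hours of retinoic acid, 6 hours without treatment and 8 hours of BMP4, a bone morphogenetic protein, or of the agent that the labels call LDN. For the RA groups the labels give the 18 hours alone, so RA and the other arms may also differ in time of collection, and comparisons with RA cannot separate treatment from time. Of the 6 groups, 5 held 3 libraries each. The FOXA2-positive LDN group held 2, numbered 2 and 3, and a library numbered 1 of that group was not analysed here. Each library held between 8435845 and 10796136 counts assigned to genes (median 9785138) and between 16139 and 18457 genes with at least 1 count.

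The sorted fraction set the libraries apart along the first principal component of log2 CPM, the depth-normalised read count after TMM scaling. That component held 24.9% of the variance, with FOXA2-negative libraries between -20.8 and -6.91 and FOXA2-positive libraries between 12 and 21.3. Both RA libraries numbered 1 stood apart on the second component (17.4% of the variance) at 33.3 and 32.3, against -15.8 to 4.71 for the other libraries. The same pair of libraries had the highest shares of mitochondrial counts, 6.94% in the FOXA2-negative and 7.43% in the FOXA2-positive library, against 4.81% or less elsewhere. The third component, with 9.6% of the variance, separated BMP4 libraries (8.93 to 13.96) from LDN libraries (-17.2 to -10.5). Libraries of one group had Spearman correlations across genes of 0.89 to 0.952, and no pair matched within sampling noise (chi-square per degree of freedom 15.3 to 53.3).

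**Figure D1:**
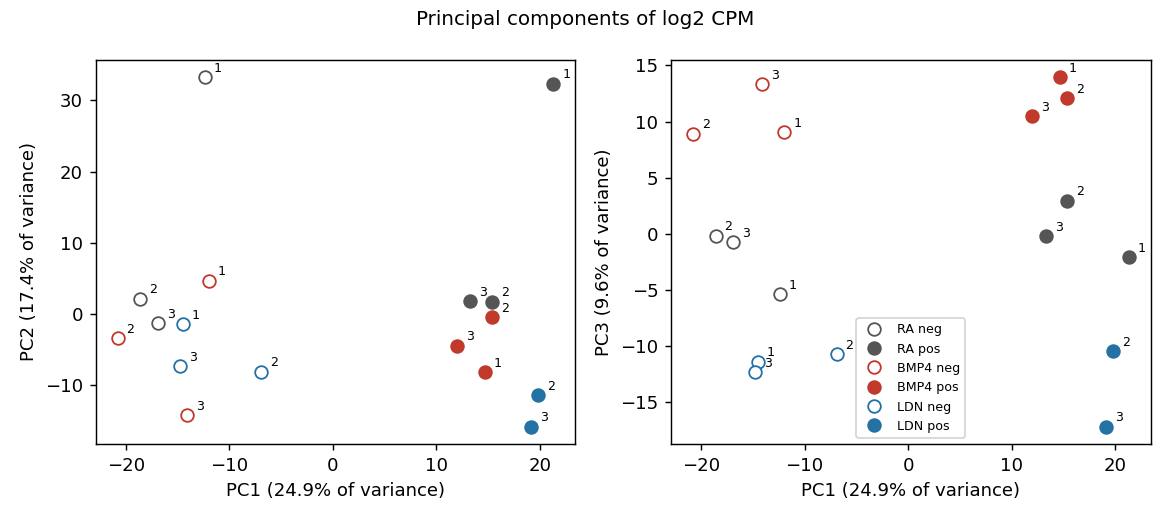
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM over genes with a mean of at least 20 CPM, 1 point per library with its replicate number. Colours give the treatment (grey RA, red BMP4, blue LDN), and open and filled points the FOXA2-negative and FOXA2-positive fractions, which component 1 separates.

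Foxa2 itself (ENSMUSG00000037025, chromosome 2, 148042877 to 148046969, minus strand, mm10) checks the sort. It stood at 23.0 ± 6.82 CPM (SD, n = 3) in RA FOXA2-positive cells and at 0.31 ± 0.10 CPM (n = 3) in RA FOXA2-negative cells, a log2 fold change of 6.15 ± 0.85 (SE; edgeR adjusted p = 0.000319). In BMP4 the values were 25.9 ± 2.80 and 0.775 ± 0.860 CPM (n = 3 each; log2 fold change 5.07 ± 0.78, adjusted p = 0.0012). In LDN they were 42.0 ± 3.17 (n = 2) and 1.85 ± 1.61 CPM (n = 3; 4.50 ± 0.75, adjusted p = 0.00268). Shh, the ventral signal made by the mature floor plate, had 0 counts in 5 groups and 11 counts in LDN FOXA2-positive cells (0.636 ± 0.632 CPM, n = 2). It was left out by the expression filter, and at this depth a group with 0 counts allows up to 0.0985 to 0.105 CPM, where 3 counts over the group are the floor. Intervals and floors given here cover counting error only.

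The first question was how FOXA2-positive cells differ from their FOXA2-negative neighbours after retinoic acid alone. In RA, 212 genes differed at an adjusted p under 0.05, 66 higher and 146 lower in FOXA2-positive cells. FOXA2-positive cells held more Ccnd2, the cell cycle gene cyclin D2 (822 ± 63.6 against 287 ± 14.2 CPM, SD, n = 3 each; log2 fold change 1.52 ± 0.16, SE, adjusted p = 7.45e-06). The growth factor gene Fgf3 rose from 6.37 ± 1.70 to 40.9 ± 9.88 CPM (2.68 ± 0.46, adjusted p = 0.00232), and Cpn1 (ENSMUSG00000025196, chromosome 19, 43956307 to 43986556, minus strand), a carboxypeptidase N subunit, from 6.51 ± 1.70 to 48.4 ± 9.70 CPM (2.89 ± 0.51, adjusted p = 0.00438). Sox17, an endoderm transcription factor that also acts in endothelium, rose by 2.72 ± 0.56 (adjusted p = 0.0101). Higher too were Prickle1 (2.07), the phosphatase gene Ptpn12 (1.89), the Notch effector Hes1 (1.20), the Hedgehog receptor gene Ptch1 (1.83, adjusted p = 0.0396), the N-cadherin gene Cdh2 (1.58) and the Wnt target Sp5 (1.85). Genes of the pluripotent state fell: Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, plus strand), which encodes OCT4, from 59.0 ± 13.6 to 12.6 ± 3.46 CPM (-2.23 ± 0.29, adjusted p = 0.000106). Zfp42 (REX1) fell from 93.1 ± 16.4 to 19.7 ± 2.15 CPM (-2.24 ± 0.26, adjusted p = 1.35e-05) and Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633, plus strand) from 15 ± 1.5 to 0.648 ± 0.555 CPM (-4.48 ± 0.89, adjusted p = 0.00839). Utf1 (-2.13) and Dppa5a (-1.06) were lower as well, as were the water and glycerol channel gene Aqp3 (-5.18), the neuronal tubulin gene Tubb3 (-2.16) and the TGF-beta family ligand gene Nodal (-3.16).

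Among the gene lists, pluripotency stood out in RA: of 14 measured members 5 were called lower and none higher, 13 were lower when adjusted over the list alone, and the median log2 fold change was -2.23 (camera adjusted p = 7.47e-30, and adjusted p = 0.000299 with an estimated correlation). The surface ectoderm list fell (11 measured, Cdh1, Tfap2a and Tfap2c called lower, 6 when adjusted over the list alone, median -0.90, adjusted p = 4.26e-08, and 0.00367 with an estimated correlation). Tfap2c, an AP-2 transcription factor also expressed in pluripotent and germ cells, went from 56.0 ± 13.6 to 11.1 ± 0.504 CPM (n = 3 each). Anterior Hox genes, paralogues 1 to 5, were higher: all 15 measured members had positive log2 fold changes (median 0.54, adjusted p = 9.57e-06, and 0.0141 with an estimated correlation), with 1 member called over all genes and 2 when adjusted over the list alone. Through the sort itself Foxa2 was bound to be higher, and it was not taken out of the floor plate list in any treatment. The call of that list between fractions therefore says little about its other members. The list had Foxa2 as its 1 called gene among 10 measured (median 0.64, adjusted p = 0.00416), a call lost at adjusted p = 0.126 with an estimated correlation. Calls for 4 further lists were lost in the same way: neural progenitors (adjusted p = 0.116 with an estimated correlation, Cdh2 called), Wnt targets (0.126, Sp5 called), retinoic acid response (0.152, 1 member called higher and Stra8 lower) and BMP ligands, receptors and SMADs (0.126, no member called). Id1, a BMP target, differed by 0.40 (adjusted p = 0.665).

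With the replicate number as a block within treatment, 362 genes were called in RA (140 higher, 222 lower), 206 of them among the 212. Without RA FOXA2-negative library 2 the count was 104, without FOXA2-positive library 2 it was 127 and without FOXA2-positive library 3 it was 134. Leaving out both RA libraries numbered 1, which carried the higher mitochondrial shares, gave 109 genes, 86 of them among the 212. Foxa2, Cpn1, Fgf3, Prickle1, Ptpn12, Hes1, Pou5f1, Zfp42, Utf1, Dppa5a, Tfap2c, Tfap2a, Aqp3 and Tubb3 kept their calls with each RA library left out in turn. Nanog lost its call without FOXA2-positive library 3 (adjusted p = 0.0547), and Sp5 (0.0735) and Sox17 (0.0825) without FOXA2-negative library 2. Cdh2 lost its call without FOXA2-positive library 1 (0.196) and FOXA2-negative libraries 2 (0.14) and 3 (0.138). Of the 6 libraries, 4 each ended the calls of Ptch1 and Nodal when left out and 3 those of Cdh1 and Stra8.

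The same comparison after BMP4 gave 164 genes, 57 higher and 107 lower in FOXA2-positive cells. Pcbd1, a pterin dehydratase that also serves as a cofactor of HNF1 transcription factors, rose from 3.55 ± 1.93 to 28.3 ± 2.22 CPM (SD, n = 3 each; log2 fold change 3.0 ± 0.44, SE, adjusted p = 0.000671). Sp5 rose from 3.84 ± 1.45 to 19 ± 5.7 CPM (2.31 ± 0.39, adjusted p = 0.00212), and the adhesion gene Flrt3 by 2.02 ± 0.31 (adjusted p = 0.00075). Cpn1 (2.31), the keratin gene Krt19 (1.63, adjusted p = 0.0169) and the laminin gene Lamb1 (0.92) were higher as well. Spp1, which encodes the secreted protein osteopontin, fell from 52.0 ± 12.6 to 3.11 ± 1.36 CPM (-4.05 ± 0.56, adjusted p = 0.000524). Pou5f1 fell from 52.2 ± 11.4 to 13.3 ± 2.22 CPM (-1.97 ± 0.29, adjusted p = 0.000671), Nanog from 21.6 ± 12.8 to 0.998 ± 1.34 CPM (-4.41 ± 0.87, adjusted p = 0.00928) and Tfap2c from 56.6 ± 6.27 to 21.8 ± 4.62 CPM (-1.38 ± 0.25, adjusted p = 0.00406). Zfp42 (-1.49), Utf1 (-1.39), Dppa5a (-0.86) and Fgf4 (-3.72) fell too. The pluripotency list again fell (14 measured, 6 called lower; adjusted over the list alone 10 lower and Tbx3 higher; median -1.73, adjusted p = 1.02e-16, and 0.00526 with an estimated correlation). All 11 measured Wnt targets had positive log2 fold changes (median 0.54, Sp5 called, 3 when adjusted over the list alone, adjusted p = 1.11e-05, and 0.0145 with an estimated correlation). The surface ectoderm list fell (Tfap2c called, median -0.71, adjusted p = 1.47e-05, and 0.0145 with an estimated correlation) and Hox paralogues 1 to 5 rose (1 member called, median 0.55, adjusted p = 0.00082, and 0.0382 with an estimated correlation).

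A further 8 lists were called in BMP4 at the preset correlation and lost with an estimated one, at adjusted p between 0.0924 for basement membrane and 0.271 for G2/M phase, with Eph receptors and ephrins, neural progenitors, endoderm, retinoic acid response, floor plate and Notch pathway between them. Id1 differed by -0.04 (adjusted p = 0.999). The count of 164 fell to 60 without BMP4 FOXA2-negative library 2, to 82 without FOXA2-positive library 1, to 78 without FOXA2-positive library 2 and to 93 without FOXA2-positive library 3. Foxa2, Pcbd1, Sp5, Flrt3, Spp1, Pou5f1, Zfp42 and Tfap2c kept their calls with each BMP4 library left out. Nanog lost its call without FOXA2-positive library 1 (adjusted p = 0.0708) or FOXA2-negative library 2 (0.0783). Of the 6 libraries, 5 each ended the call of Cpn1 when left out, 4 those of Lamb1, Fgf4 and Dppa5a, 3 that of Krt19 and 2 that of Utf1.

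After LDN, 177 genes differed, 51 higher and 126 lower in FOXA2-positive cells. Gpc3, the heparan sulphate proteoglycan gene glypican 3, rose from 63.8 ± 8.43 (SD, n = 3) to 350 ± 93.9 CPM (n = 2; log2 fold change 2.46 ± 0.26, SE, adjusted p = 1.14e-05). Cpn1 rose from 7.95 ± 5.66 to 79.0 ± 9.73 CPM (3.31 ± 0.54, adjusted p = 0.00268), Sox17 from 7.82 ± 2.96 to 45.5 ± 17 CPM (2.54 ± 0.57, adjusted p = 0.0241), and Id3 from 24.1 ± 5.08 to 51.5 ± 2.26 CPM (1.09, adjusted p = 0.00497). The semaphorin and VEGF receptor gene Nrp1 was higher as well (2.10). Tfap2c fell from 82.0 ± 17.8 to 6.47 ± 1.15 CPM (-3.66 ± 0.32, adjusted p = 3.61e-07), the stress gene Gadd45g from 87.8 ± 45.9 to 3.86 ± 0.502 CPM (-4.51 ± 0.59, adjusted p = 0.000206) and Pou5f1 from 64.1 ± 13.6 to 9.12 ± 3.70 CPM (-2.80 ± 0.36, adjusted p = 6.16e-05). Nanog, at 9.23 ± 3.67 CPM in FOXA2-negative cells, had 0 counts in both FOXA2-positive libraries, at least 58.0-fold lower. Tbx3, a T-box gene of the naive pluripotent state and a BMP target, fell from 15.8 ± 3.88 to 4.74 ± 0.399 CPM (-1.74 ± 0.29, adjusted p = 0.00193). Zfp42 (-2.07), Utf1 (-2.26), Fgf4 (-4.50), Dlx3 (-2.63) and the keratin genes Krt8 (-1.47) and Krt18 (-0.83) fell too. The pluripotency list (14 measured, 7 called lower, 12 when adjusted over the list alone, median -2.17, adjusted p = 1.3e-26, and 0.000488 with an estimated correlation) and the surface ectoderm list (Dlx3, Tfap2a and Tfap2c called, median -0.75, adjusted p = 2.1e-09, and 0.0018 with an estimated correlation) fell. Hox paralogues 1 to 5 rose (median 0.84, adjusted p = 7.52e-06, and 0.0118 with an estimated correlation).

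In LDN 5 lists lost their call with an estimated correlation: floor plate, neural progenitors and Notch pathway (each at adjusted p = 0.0931 with an estimated correlation), BMP ligands, receptors and SMADs (0.122) and Eph receptors and ephrins (0.249; median 0.61, with Epha2 called lower). The count of 177 fell to 104 without LDN FOXA2-negative library 1, to 105 without FOXA2-negative library 3, to 81 without FOXA2-positive library 2 and to 69 without FOXA2-positive library 3. In the last 2 cases 1 library stands for its group and is assumed to vary like the others. Foxa2, Cpn1, Gpc3, Gadd45g, Pou5f1, Zfp42 and Tfap2c kept their calls with each LDN library left out. Without FOXA2-positive library 2 the adjusted p rose to 0.0917 for Nanog, and without FOXA2-positive library 3 to 0.0771 for Nanog, 0.0676 for Id3 and 0.0557 for Tbx3. Sox17 lost its call without any 1 of the 5 libraries, Krt18 and Epha2 without any of 4, Nrp1, Tfap2a, Krt8 and Fgf4 without any of 3, Dlx3 without either of 2 and Utf1 without 1.

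Across the 3 treatments, 16 genes were called higher and 42 lower in FOXA2-positive cells every time, of 352 called at least once. The 16 included Arhgef28, Ccnd2, Cpn1, Dact2, Dennd5b, Emb, Flrt3, Foxa2, Gpc3, Gprc5c, Lpar6, Nnat, Prtg, Sox4 and Tagln2. The 42 included Pou5f1, Nanog, Zfp42, Utf1, Dppa5a, Tfap2c, Aqp3, Spp1, Sfn, Tdrd12 and Tex19.1. RA and BMP4 shared 29 higher and 72 lower calls (independent lists would share 0.21 and 0.88), RA and LDN 22 and 66 (0.19 and 1), and no gene was called in opposite directions in either pair. Of the 212 RA genes, 206 pointed the same way in BMP4 and 207 in LDN. The shared lower genes also held Zscan4c, a gene of the 2-cell-like state. It had 0 counts in the FOXA2-positive cells of BMP4 (at least 304-fold lower) and LDN (at least 71.6-fold lower), and in RA its ratio was 1480 with a counting interval of 266 to 58700. The LDN bound rests on FOXA2-negative libraries that spread widely (11.4 ± 14.4 CPM, SD, n = 3). The LDN call of Zscan4c was also lost under 1 setting other than a left-out library. Zscan4 and Usp17l genes belong to families of near-identical copies, so how their reads were split among members is uncertain.

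**Figure D2:**
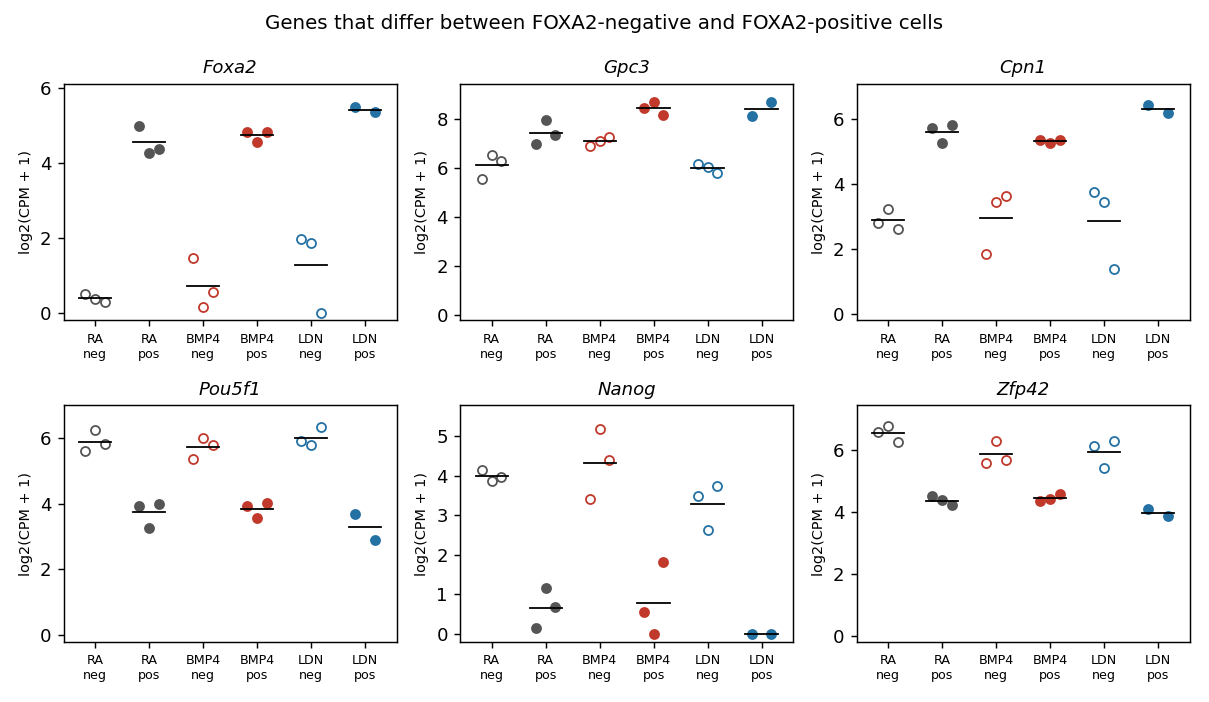
log2(CPM + 1) of 6 genes in each library (points) with the group mean (line), for FOXA2-negative (open) and FOXA2-positive (filled) cells in RA (grey), BMP4 (red) and LDN (blue). Foxa2, Gpc3 and Cpn1 lie higher and Pou5f1, Nanog and Zfp42 lower in FOXA2-positive cells in each treatment.

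The fold changes between fractions also followed chromosomes, which was examined after the data were seen. Over genes of at least 20 CPM, the median log2 fold change of FOXA2-positive against FOXA2-negative cells on chromosome 6 (335 genes) was 0.31 in RA, 0.34 in BMP4 and 0.24 in LDN. On chromosome 8 (407 genes) it was -0.31, -0.30 and -0.27, and on the 18 other chromosomes it lay between -0.05 and 0.10. Between 75.2% and 86.9% of the chromosome 6 genes were higher, and between 78.9% and 84.8% of the chromosome 8 genes were lower. The Y-linked genes Ddx3y, Eif2s3y, Uty, Zfy1 and Kdm5d had negative log2 fold changes in each treatment. Ddx3y, an RNA helicase gene, stood at 8.00 ± 2.37 CPM in FOXA2-positive and 38.8 ± 6.33 CPM in FOXA2-negative RA cells (SD, n = 3 each; -2.28 ± 0.37, SE, adjusted p = 0.00111), was called in BMP4 (-1.89, adjusted p = 0.00731) and missed the threshold in LDN (-0.95, adjusted p = 0.364). Chromosomes 6, 8 and Y held 38 of the 212 RA calls, 36 of the 164 BMP4 calls and 27 of the 177 LDN calls. Tests on genes of the other chromosomes gave 171, 126 and 147 calls, all of them among the 212, 164 and 177. Nanog lies on chromosome 6 and Cdh1 on chromosome 8. Without these chromosomes the Hox list kept its call in all 3 treatments, but 9 of the 79 list calls over all contrasts were lost, among them retinoic acid response in RA, BMP ligands, receptors and SMADs in LDN and Hox paralogues in LDN against RA. So were 4 calls of named genes: Fstl1 in RA, Hes1 in BMP4, and Ncam1 in LDN against RA and in BMP4 against LDN in FOXA2-positive cells.

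**Figure D3:**
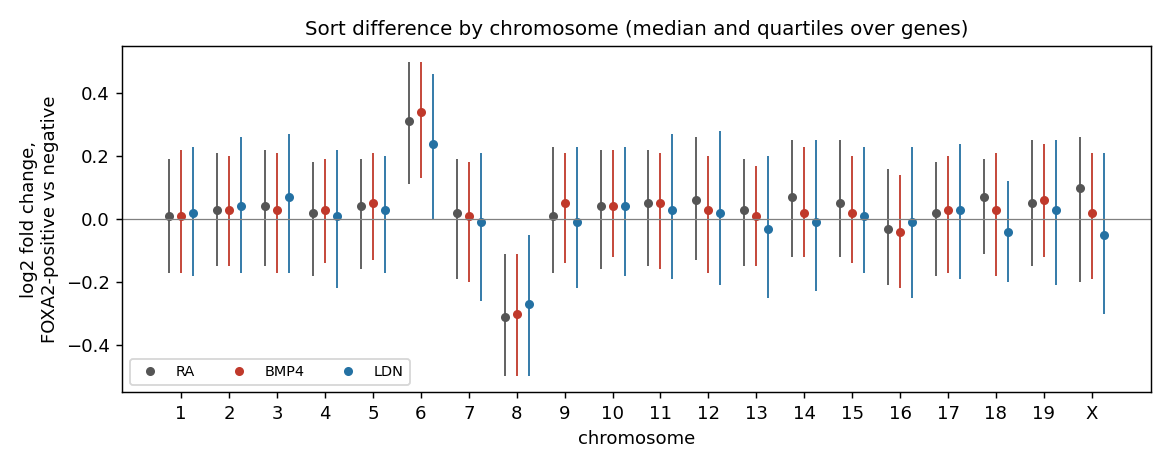
Median (point) and quartiles (line) over genes of the log2 fold change, FOXA2-positive against FOXA2-negative, for each autosome and X in RA (grey), BMP4 (red) and LDN (blue). Chromosome 6 lies above 0 at 0.24 to 0.34 and chromosome 8 below 0 at -0.31 to -0.27.

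The next question was what BMP4 after retinoic acid changed within each fraction. In FOXA2-negative cells 14 genes differed between BMP4 and RA, 10 higher and 4 lower after BMP4. The ID genes, which encode inhibitors of basic helix-loop-helix factors and are transcribed directly under BMP signalling, rose. Id1 (ENSMUSG00000042745, chromosome 2, 152736251 to 152737410, plus strand) went from 55.6 ± 6.04 to 256 ± 22.1 CPM (SD, n = 3 each; log2 fold change 2.20 ± 0.29, SE, adjusted p = 0.000498). Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755, plus strand) went from 118 ± 18.6 to 376 ± 89.3 CPM (1.67 ± 0.18, adjusted p = 9.93e-06), Id2 from 44.1 ± 13.6 to 139 ± 15.3 CPM (1.65 ± 0.22, adjusted p = 0.000498) and Tbx3 (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724, plus strand) from 35.9 ± 7.17 to 105 ± 12.1 CPM (1.55 ± 0.23, adjusted p = 0.00116). Ccnd2 (0.87, adjusted p = 0.0371) and the netrin receptor gene Unc5b (1.54, adjusted p = 0.0441) were also higher, and the predicted gene Gm17251 fell (-3.83, adjusted p = 9.49e-06). The remaining calls were Emb, Lbr, Slc30a3 and Ramp2 (higher) and Med16, Klhdc7a and G0s2 (lower). All 16 measured BMP-SMAD targets had positive log2 fold changes (3 called, 11 when adjusted over the list alone, median 1.66, adjusted p = 4.85e-36, and 8.99e-07 with an estimated correlation). Msx1 (1.67, adjusted p = 0.0605) and Msx2 (1.47, adjusted p = 0.368) were among those not called over all genes. BMP antagonists (0.126) and neural progenitors (0.234, median -0.62) lost their calls at these adjusted p with an estimated correlation.

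Leaving out 1 library moved the count of 14 to 7 (RA FOXA2-negative library 1, BMP4 FOXA2-negative library 2 or BMP4 FOXA2-negative library 3), 5 (RA FOXA2-negative library 2) or 6 (RA FOXA2-negative library 3), and without both RA libraries numbered 1 it was 9. Id1, Id2, Id3 and Tbx3 kept their calls each time 1 library was left out, while Ccnd2, Unc5b, Lbr and Med16 lost theirs without any 1 of the 6 libraries and Emb without any of 5. In a fit to these 6 libraries alone the count was 3, and Id2 and Tbx3 were among the genes that lost their call under a setting other than a left-out library.

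In FOXA2-positive cells 14 genes differed between BMP4 and RA, 12 higher and 2 lower after BMP4. Msx2 (ENSMUSG00000021469, chromosome 13, 53466884 to 53473074, minus strand), a homeobox gene of the dorsal neural tube, rose from 2.7 ± 1.5 to 26.1 ± 1.72 CPM (SD, n = 3 each; log2 fold change 3.27 ± 0.45, SE, adjusted p = 0.000701). Tbx3 rose from 24.7 ± 0.414 to 170 ± 47.8 CPM (2.78 ± 0.24, adjusted p = 1.59e-07), Tfap2a from 11.8 ± 4.89 to 88.0 ± 36.3 CPM (2.89, adjusted p = 0.00394) and the inhibitory SMAD gene Smad7 from 7.71 ± 2.43 to 38.1 ± 11.8 CPM (2.30 ± 0.45, adjusted p = 0.0316). Id1 (1.76 ± 0.28, adjusted p = 0.00529), Id2 (1.31 ± 0.22, adjusted p = 0.00587) and Id3 (1.39, adjusted p = 0.000172) rose, as did the keratin gene Krt18, from 94.4 ± 24.1 to 251 ± 4.92 CPM (1.41 ± 0.17, adjusted p = 0.000131). Unc5b, Zfp36l3 and Pced1b were also higher. Pax6, a neural progenitor transcription factor, fell from 62.4 ± 5.05 to 25.7 ± 4.79 CPM (-1.28 ± 0.24, adjusted p = 0.023) and Slc2a1, the glucose transporter GLUT1, from 595 ± 21.0 to 340 ± 37.0 CPM (-0.81 ± 0.13, adjusted p = 0.00394). Foxa2 differed by 0.17 (adjusted p = 1.0). All 16 measured BMP-SMAD targets had positive log2 fold changes (5 called, 10 when adjusted over the list alone, median 1.63, adjusted p = 2.69e-40, and 4.98e-07 with an estimated correlation).

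Another 9 lists were called here and lost with an estimated correlation. Endoderm (Krt18 called), surface ectoderm (Tfap2a called, median 0.00), dorsal neural tube (Msx2 called) and neural progenitors, lower (Pax6 called), each had an adjusted p of 0.0523 with an estimated correlation, and pluripotency (Tbx3 called) and Wnt targets 0.0528. Neural crest had 0.0903, intermediate neural progenitors 0.123, with a median of -0.80 against a mean of 0.25, and Eph receptors 0.176. The count of 14 was 9 without RA FOXA2-positive library 1 or library 2, 7 without BMP4 FOXA2-positive library 1 and 9 without both RA libraries numbered 1. Msx2, Tbx3, Krt18, Id3 and Zfp36l3 kept their calls with each library left out, while Smad7 lost its call without any 1 of the 6 libraries, Pax6 without any of 5 and Unc5b without any of 3. Without RA FOXA2-positive library 2 the adjusted p was 0.0648 for Id1 and 0.058 for Id2, without RA FOXA2-positive library 3 it was 0.0611 for Id1 and Id2 and 0.0529 for Tfap2a, and without BMP4 FOXA2-positive library 1 it was 0.0613 for Id2 and 0.0669 for Slc2a1.

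LDN was compared with RA in the same way. In FOXA2-negative cells 7 genes differed, 2 higher and 5 lower after LDN. Id1 fell from 55.6 ± 6.04 to 5.07 ± 1.45 CPM (SD, n = 3 each; log2 fold change -3.46 ± 0.32, SE, adjusted p = 1.49e-06), Id2 from 44.1 ± 13.6 to 4.18 ± 1.32 CPM (-3.39 ± 0.25, adjusted p = 1.03e-08) and Id3 from 118 ± 18.6 to 24.1 ± 5.08 CPM (-2.29 ± 0.19, adjusted p = 3.11e-08). Gm17251 fell by 4.26 on the log2 scale (adjusted p = 5.74e-07). Slc2a1 rose from 399 ± 35.4 to 689 ± 46.8 CPM (0.79 ± 0.13, adjusted p = 0.00767) and the microtubule-associated gene Map1b by 0.90 ± 0.16 (adjusted p = 0.0242). BMP-SMAD targets fell as a list (3 called; adjusted over the list alone 10 lower and Smad9 and Atoh8 higher; median -1.43, adjusted p = 6.5e-25, and 6.17e-06 with an estimated correlation). Hox paralogues 1 to 5 fell too, with 13 of 15 log2 fold changes negative (1 member called, median -0.68, adjusted p = 1.51e-05, and 0.0184 with an estimated correlation). Neural progenitors (higher, 0.0526), dorsal neural tube (lower, 0.0526) and Hox paralogues 6 to 9 (lower, 0.21) lost their calls at these adjusted p with an estimated correlation. The count of 7 became 4 without RA FOXA2-negative library 3 and 11 without LDN FOXA2-negative library 1, and 9 without both RA libraries numbered 1. Id1, Id2 and Id3 kept their calls throughout. Slc2a1 lost its call without RA FOXA2-negative library 2 (adjusted p = 0.0674), RA FOXA2-negative library 3 (0.0819) and LDN FOXA2-negative library 2 (0.0664), and Map1b lost its call without any of 5 libraries.

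In FOXA2-positive cells 37 genes differed between LDN and RA, 13 higher and 24 lower after LDN. Id1 fell from 73.6 ± 8.26 (SD, n = 3) to 8.56 ± 7.85 CPM (n = 2; log2 fold change -3.07 ± 0.36, SE, adjusted p = 0.000106), Id2 from 54.9 ± 2.38 to 6.18 ± 0.229 CPM (-3.15 ± 0.29, adjusted p = 1.01e-06) and Tbx3 from 24.7 ± 0.414 to 4.74 ± 0.399 CPM (-2.37 ± 0.29, adjusted p = 9.99e-05). Id3 (-1.94 ± 0.21, adjusted p = 1.35e-05) and Smad7 (-2.85 ± 0.59, adjusted p = 0.032) fell as well. Msx2 went from 2.7 ± 1.5 CPM to 0 counts, at least 17-fold lower (adjusted p = 0.000759). Ncam1, a neural adhesion molecule, rose from 282 ± 51.7 to 623 ± 82.1 CPM (1.15 ± 0.24, adjusted p = 0.0499), Slc2a1 from 595 ± 21.0 to 1016 ± 97.6 CPM (0.77 ± 0.14, adjusted p = 0.013) and Maml2, a Notch coactivator gene, by 2.04 ± 0.33 (adjusted p = 0.00367). BMP-SMAD targets fell (5 called, 8 when adjusted over the list alone, median -1.31, or -1.30 with genes at 0 set to their bound, adjusted p = 6.12e-17, and 4.35e-05 with an estimated correlation). Hox paralogues 1 to 5, lower, and neural progenitors, higher, lost their calls at adjusted p = 0.0947 with an estimated correlation each, Notch pathway, higher, at 0.0555, dorsal neural tube, lower, at 0.0986 and pluripotency, lower, at 0.245. Foxa2 differed by 0.87 (adjusted p = 0.701). The count of 37 was 23 without RA FOXA2-positive library 1, 18 without RA FOXA2-positive library 3, 22 without LDN FOXA2-positive library 2 and 9 without LDN FOXA2-positive library 3. It was 42 without both RA libraries numbered 1, and 9 in a fit to these 5 libraries alone. Without a filter it was 294, with 168 higher and 126 lower. Id1, Id2, Id3, Tbx3 and Msx2 kept their calls with each library left out, but in the fit to these 5 libraries alone Id1 and Tbx3 (adjusted p = 0.0707 each) and Msx2 (0.303) lost theirs. Ncam1 lost its call without any 1 of the 5 libraries, Slc2a1 without any of 4, Smad7 without any of 3 and Maml2 without 1.

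Both arms share the RA libraries, so some likeness between them is built in. Over 6669 genes the log2 fold changes of BMP4 against RA and of LDN against RA had a correlation of 0.49 in FOXA2-negative cells and 0.48 in FOXA2-positive cells, where unchanged groups simulated against the same controls gave 0.50 and 0.46. The covariances were 0.052 and 0.067 against simulated 0.038 and 0.039. Among called genes the 2 arms went opposite ways: Id1, Id2 and Id3 in FOXA2-negative cells (independent lists would share 0.0033), and in FOXA2-positive cells 8 genes, among them Id1, Id2, Id3, Msx2, Slc2a1, Smad7 and Tbx3 (0.018). Gm17251 in FOXA2-negative cells was the 1 gene called in the same direction, lower in both. No split of 3 control libraries leaves 2 for each arm, so none was run, and part of any likeness may come from the shared libraries.

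The direct comparison of BMP4 with LDN, at matched times, asked which genes set the 2 arms apart. In FOXA2-negative cells 35 genes differed, 22 higher and 13 lower in BMP4. Id1 was higher by 5.66 ± 0.35 on the log2 scale (SE, adjusted p = 4.92e-10), Id2 by 5.05 ± 0.27 (adjusted p = 1.76e-12) and Id3 by 3.96 ± 0.20 (adjusted p = 8.91e-13). Msx1, a dorsal homeobox gene, stood at 648 ± 263 CPM in BMP4 and 88.3 ± 22.3 CPM in LDN (SD, n = 3 each; 2.88 ± 0.32, adjusted p = 0.000293), Msx2 at 26.6 ± 3.03 and 3.56 ± 0.384 CPM (2.90 ± 0.44, adjusted p = 0.00104) and Smad7 at 27.6 ± 6.08 and 2.91 ± 1.14 CPM (3.23 ± 0.47, adjusted p = 0.000544). Tbx3 (2.73), the BMP pseudoreceptor gene Bambi (3.29), Gata3 (2.34), Dlx5 (2.43), Pax3 (2.56) and Tfap2a (163 ± 9.17 against 27.4 ± 6.83 CPM) were higher too. Sox1, a neural progenitor gene, was lower (5.47 ± 1.36 against 30.9 ± 8.05 CPM; -2.50 ± 0.41, adjusted p = 0.00253), as were Stra6, the receptor for retinol uptake (17.3 ± 6.48 against 72.9 ± 8.47 CPM; -2.07 ± 0.32, adjusted p = 0.00116), Slc2a1 (257 ± 33.9 against 689 ± 46.8 CPM; -1.42 ± 0.13, adjusted p = 1.92e-07) and a second glucose transporter, Slc2a3 (288 ± 21.7 against 506 ± 32.1 CPM; -0.81 ± 0.14, adjusted p = 0.00327). All of these except Bambi, Dlx5 and Pax3 kept their calls with each library left out, and no left-out library moved the count by more than 1.5 times.

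In lists, BMP-SMAD targets were higher in FOXA2-negative BMP4 cells (8 called, 13 when adjusted over the list alone, median 3.06, adjusted p = 1.42e-98, and 4.49e-09 with an estimated correlation). Neural progenitors were lower (Sox1 called, 7 when adjusted over the list alone, median -0.95, adjusted p = 6.09e-11, and 0.00175 with an estimated correlation). Higher with either correlation were Hox paralogues 6 to 9 (2 higher when adjusted over the list alone, adjusted p = 0.0478 with an estimated correlation), Hox paralogues 1 to 5 (median 0.34, 0.0284) and BMP antagonists (0.0486). The dorsal neural tube list was also called higher (0.0238) with a median of -0.21 against a mean of 0.78. Pax3, Msx1 and Msx2 were its called members, and Msx1 and Msx2 are also in the BMP-SMAD target list. Intermediate neural progenitors, lower (0.0736), Notch pathway, lower (0.0552), proneural genes, lower (0.109), and surface ectoderm, tested higher with a median of -0.23 and a mean of -0.29 (0.129; Gata3, Tfap2a and Dlx5 called), lost their calls at these adjusted p with an estimated correlation.

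In FOXA2-positive cells 57 genes differed between BMP4 and LDN, 42 higher and 15 lower in BMP4. Tbx3 stood at 170 ± 47.8 CPM in BMP4 (SD, n = 3) and 4.74 ± 0.399 CPM in LDN (n = 2; log2 fold change 5.16 ± 0.32, SE, adjusted p = 1.93e-10). Msx2, at 26.1 ± 1.72 CPM in BMP4, had 0 counts in LDN, at least 164-fold higher in BMP4 (adjusted p = 1.8e-07), and the BMP antagonist gene Nog (18.8 ± 3.45 CPM) at least 118-fold (adjusted p = 0.00921). Id1 (4.84 ± 0.39, adjusted p = 1.07e-07), Id2 (4.46 ± 0.31), Id3 (3.33 ± 0.23), Smad7 (5.15 ± 0.63, adjusted p = 3.46e-05), Tfap2a (4.08 ± 0.53, adjusted p = 0.000518), Gata3 (2.73) and Gata2 (3.82) were higher. So were the keratin genes Krt19 (2.7 ± 0.43, adjusted p = 0.00111) and Krt18 (0.88), Tfap2c (1.75, adjusted p = 0.00284) and the Wnt effector Lef1 (2.39 ± 0.35, adjusted p = 0.000469). Slc2a1 was lower (340 ± 37.0 against 1016 ± 97.6 CPM; -1.58 ± 0.14, adjusted p = 1.12e-07), as were Ncam1 (291 ± 89.6 against 623 ± 82.1 CPM; -1.10 ± 0.24, adjusted p = 0.0497) and the neural progenitor gene Sox3 (8.84 ± 3.43 against 34.1 ± 4.13 CPM; -1.95 ± 0.42, adjusted p = 0.0316). Foxa2 differed by -0.70 (adjusted p = 0.875) and Sox1 by -1.74 (adjusted p = 0.0937). BMP-SMAD targets were higher (9 called, 12 when adjusted over the list alone, median 3.08, adjusted p = 3.21e-66, and 3.46e-08 with an estimated correlation) and neural progenitors lower (Ncam1 and Sox3 called, 6 when adjusted over the list alone, median -0.94, adjusted p = 1.63e-10, and 0.00214 with an estimated correlation).

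Of the other lists in FOXA2-positive cells, dorsal neural tube (Msx1 and Msx2 called, median 0.78, adjusted p = 0.00535 with an estimated correlation), pluripotency (Tbx3 called, median 0.54, 0.01), endoderm (Krt18 and Krt19 called, median 0.69, or 0.38 with genes at 0 set to their bound, 0.0461) and neural crest (Tfap2a called, 0.0461) were higher in BMP4. Surface ectoderm was higher (Gata3, Tfap2a and Tfap2c called, 0.0058) with a median of 0.00 and a mean of 0.66, and Notch pathway was lower (0.0368). Msx1, Msx2 and Gata3 are also in the BMP-SMAD target list, and Tfap2a is in both neural crest and surface ectoderm, so these calls overlap. Wnt targets, higher (0.0731; Dkk1 and Lef1 called), intermediate neural progenitors, lower (0.098), and floor plate, lower (0.122; median -0.77), lost their calls at these adjusted p with an estimated correlation. The count of 57 was 32 without LDN FOXA2-positive library 2 and 37 without library 3. Msx2, Tbx3, Smad7, the 3 ID genes, Tfap2a, Gata3, Lef1 and Slc2a1 kept their calls with each library left out. Without LDN FOXA2-positive library 2 the adjusted p was 0.146 for Nog, 0.0949 for Krt19 and 0.138 for Msx1, and without library 3 it was 0.151 for Nog, 0.0822 for Msx1 and 0.13 for Tfap2c; Krt18, Ncam1 and Sox3 lost their calls without any of 4 or 5 libraries, Gata2 without any of 3 and Dkk1 without either of 2.

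**Figure D4:**
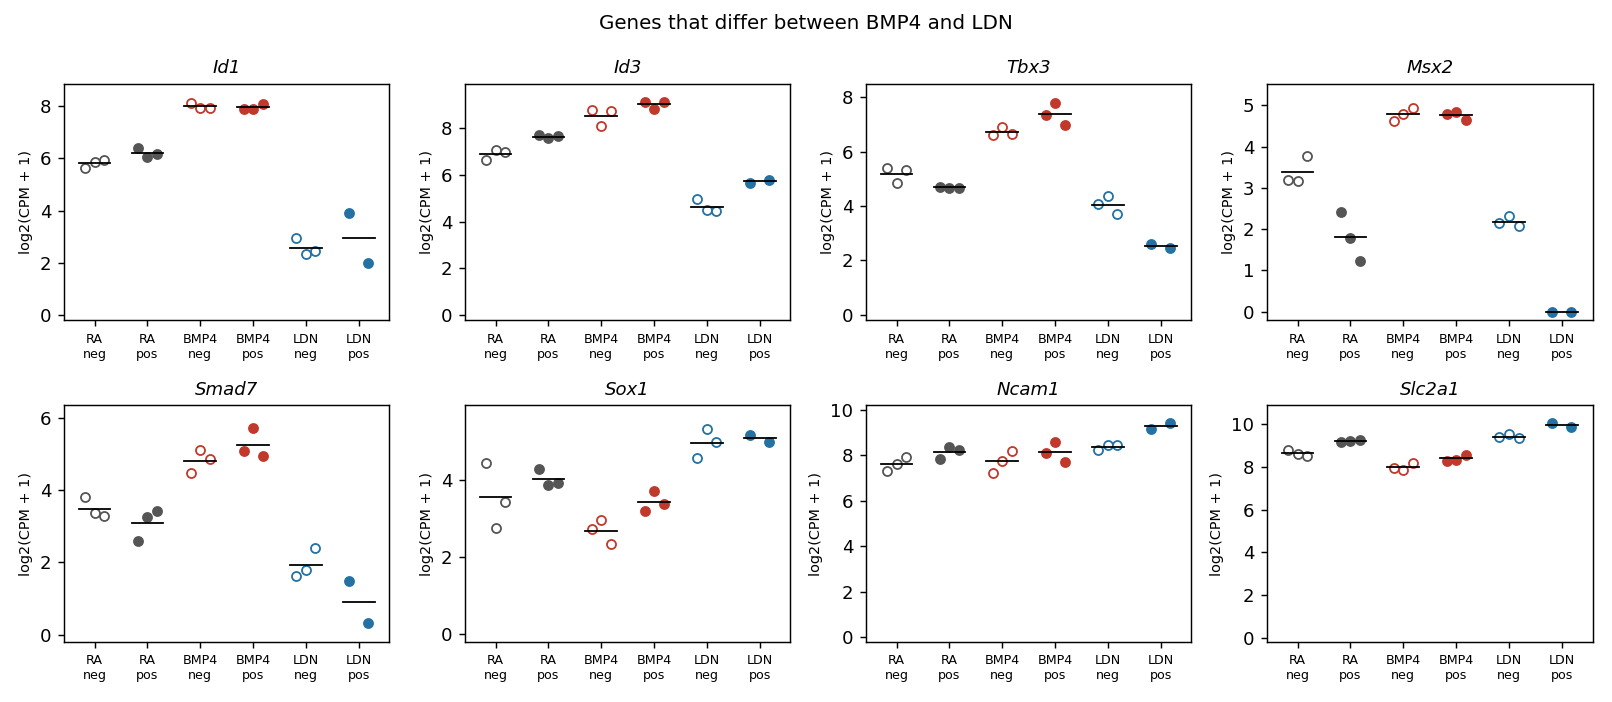
log2(CPM + 1) of 8 genes in each library (points) with the group mean (line), for FOXA2-negative (open) and FOXA2-positive (filled) cells in RA (grey), BMP4 (red) and LDN (blue). Id1, Id3, Tbx3, Msx2 and Smad7 lie higher in BMP4 than in LDN in both fractions, and Slc2a1 lies lower.

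Whether a treatment acted differently in the 2 fractions was tested as an interaction. For BMP4 against RA and for LDN against RA, 1 gene passed in each, Gm17251 (log2 difference 4.04 ± 0.54, SE, adjusted p = 0.00133, and 4.87 ± 0.57, adjusted p = 0.000102), at unadjusted p under 0.05 for 742 and 1035 genes. For BMP4 against LDN 6 genes passed, each with a higher log2 fold change in FOXA2-positive cells. Among them were Tbx3 (2.43 ± 0.36, adjusted p = 0.00438), Msx2 (adjusted p = 0.00438, with LDN FOXA2-positive cells at 0 counts), Tfap2c (2.28 ± 0.38, adjusted p = 0.013), Krt18 (1.42 ± 0.26, adjusted p = 0.0324) and Urgcp (4.73 ± 0.89, adjusted p = 0.049). In FOXA2-positive cells Tfap2c and Krt18 differed by 1.75 and 0.88, less than these values. Both thus lay lower in BMP4 than in LDN in FOXA2-negative cells, where neither was called. The interaction for Id1 was -0.44, 0.38 and -0.82 in the 3 contrasts (adjusted p = 1.0, 1.0 and 0.819). The count of 6 was 3 without BMP4 FOXA2-negative library 1, BMP4 FOXA2-positive library 2 or LDN FOXA2-negative library 3, and 2 without LDN FOXA2-positive library 2, where neither gene was among the 6. It was 5 without LDN FOXA2-positive library 3, with 2 of the 6 among them. None of the 6 kept its call with each library left out: without LDN FOXA2-positive library 2 the adjusted p was 0.0832 for Msx2 and 0.0532 for Tbx3, and without LDN FOXA2-positive library 3 it was 0.0609 for Tbx3 and 0.15 for Tfap2c. Of the 11 libraries, 10 each ended the call of Urgcp when left out, 9 that of Krt18 and 5 that of Tfap2c. The BMP4 against RA count of 1 became 2 without RA FOXA2-negative library 1 or RA FOXA2-positive library 3, and the LDN against RA count became 2 without LDN FOXA2-positive library 2. Of the genes called for BMP4 against LDN, 34 of 35 from FOXA2-negative cells and 49 of 57 from FOXA2-positive cells pointed the same way in the other fraction, and 18 were called in both.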

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

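Of the tests in this part, those on carry-over of cells and on reads of Rab11b were chosen only after the result was seen.

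Gm17251 drew attention because its change with treatment differed between the fractions, by 4.04 ± 0.54 for BMP4 against RA and by 4.87 ± 0.57 for LDN against RA (log2, SE; edgeR adjusted p = 0.00133 and 0.000102). This predicted gene (chromosome 17, 33759992 to 33761870, plus strand, mm10) stood at 166 ± 61.9 CPM in RA FOXA2-negative cells (SD, n = 3) and at group means of 5.78 to 11.6 CPM elsewhere. It overlaps Rab11b on the minus strand (33742484 to 33760530), but Rab11b did not rise with it: the log2 ratio of its mean CPM in RA FOXA2-negative cells to the group it differed from most was -0.46, which argues against reads of Rab11b as the source. Of 895 words of 31 bases in the Gm17251 transcript, 37.4% also occur in transcripts of 532 other genes, 278 of these 335 words in Rab11b, so reads shared with the remaining genes may contribute, and how such reads were handled before counting is not known. A difference that belongs to retinoic acid treatment, or to the time of collection, in FOXA2-negative cells stays open and was not tested.

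For 6 genes the log2 fold change of BMP4 against LDN was higher in FOXA2-positive than in FOXA2-negative cells, by a test of that difference. Among them were Tbx3 (2.43 ± 0.36, log2 with SE), Msx2 (8.10 ± 1.19, a fitted value that is no bound, since LDN FOXA2-positive cells had 0 counts), Krt18 (1.42 ± 0.26), Tfap2c (2.28 ± 0.38) and Urgcp (4.73 ± 0.89). For Tfap2c and Krt18 the direction turned, with BMP4 below LDN in FOXA2-negative cells, where neither was called. FOXA2-negative cells carried over into the BMP4 FOXA2-positive libraries could raise the fold change of FOXA2-positive cells in this way. From 40 genes that were lower in FOXA2-positive cells in all 3 treatments, carry-over came to a median of 4.5% of the FOXA2-negative level (quartiles 0 to 9.3%). The pattern would need between 27.1% (Tfap2c) and 156.8% (Tbx3). The 40 genes were chosen as lower in BMP4 too, which holds their share down. The share also takes levels without carry-over as equal in BMP4 and LDN FOXA2-positive cells. It therefore cannot decide for genes with a small need, such as Tfap2c. Tbx3 would need more than the whole FOXA2-negative level and Msx2 98.1% of it. For both, this argues against carry-over as the only source. A response to BMP4 or LDN that depends on the fraction may account for the pattern. This is a hypothesis that was not tested apart from these libraries. After BMP4, Msx2 stood at about the same level in both fractions. Its difference thus rests on LDN, with 0 counts in FOXA2-positive cells. For Tbx3, 1.74 of the 2.43 is likewise its lower level in FOXA2-positive than in FOXA2-negative cells in LDN. None of the 6 genes kept its call with each library left out.

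Lists also differed between fractions at the preset correlation and not with an estimated one. For BMP4 against RA these were neural crest (adjusted p = 0.0407, and 0.196 with an estimated correlation), pluripotency (0.00886 and 0.387) and basement membrane (0.00886 and 0.196). For BMP4 against LDN they were pluripotency (0.000363 and 0.178), endoderm (0.000767 and 0.178) and Wnt targets (0.0263 and 0.221).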

How the results depend on the processing

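The settings without both RA libraries numbered 1 and without chromosomes 6, 8 and Y were chosen after seeing the data. No named gene that was called in the original fit or under a setting changed direction under that setting. Turns of named genes called in neither were not recorded. No list called in the original fit changed direction under the settings run for lists. DESeq2, the stricter filter, the groups compared alone and libraries left out were not run for lists. The balance of calls did turn: without a filter LDN against RA in FOXA2-positive cells had 168 higher and 126 lower (13 and 24 with it), and its interaction had 1 higher and 5 lower with DESeq2 and 11 and 20 without a filter (1 and 0). With RLE scaling and with the stricter filter every count of called genes stayed within 1.5 times of its value. Counts moved under other settings, and where no reason is given the cause was not tested. Of 219 calls for named genes, 87 held with each library of the groups compared left out and 150 held under DESeq2, RLE, both filters and models of the compared groups alone. With an estimated correlation 29 of 79 list calls held, with RLE 79, without a filter 71 and without chromosomes 6, 8 and Y 70. Simulated 2-fold changes were recovered for 12 of 50 genes in the RA sort comparison, and for 12 of 20 above 20 CPM. Of 50 changes each, 25 were recovered at 8-fold and 39 at 16-fold, and above 20 CPM 17 of 17 and 23 of 24. For LDN against RA in FOXA2-positive cells, 5 of 18 2-fold changes above 20 CPM were recovered. Depth and spread thus limit what can be seen of small changes at any level, and of large changes in weakly expressed genes.

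DESeq2 called more genes everywhere, and its calls held all of the original ones: 456 for the sort comparison in RA (212 with edgeR), 420 in BMP4 (164) and 487 in LDN (177), 60 and 46 for BMP4 against RA in FOXA2-negative and FOXA2-positive cells (14 each), 39 and 209 for LDN against RA (7 and 37), 117 and 174 for BMP4 against LDN (35 and 57), and 5, 6 and 34 for the interactions of BMP4 with RA, LDN with RA and BMP4 with LDN (1, 1 and 6). Without a filter, when 26831 genes were tested, the counts in the same order were 466, 411, 460, 94, 100, 83, 294, 141, 196, 31, 31 and 54. Models of the compared groups alone, which hold fewer libraries, gave 127 for the RA sort, 3 and 25 for BMP4 against RA, 4 and 9 for LDN against RA, 95 for BMP4 against LDN in FOXA2-positive cells and 2 for the interaction of LDN with RA. Without both RA libraries numbered 1 the RA sort count was 109 and the counts of BMP4 against RA were 9 and 9.

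With each library left out in turn the counts ranged from 104 to 218 for the RA sort, 60 to 164 for BMP4, 69 to 163 for LDN, 5 to 10 and 7 to 15 for BMP4 against RA in FOXA2-negative and FOXA2-positive cells, 4 to 11 and 9 to 35 for LDN against RA, 25 to 35 and 32 to 53 for BMP4 against LDN, and 1 to 2, 1 to 2 and 2 to 7 for the interactions.

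With the replicate number as a block within treatment, where the numbers pair the RA libraries, the RA sort count was 362, and the block changed no other call of a named gene or list in RA. In BMP4 libraries of the same number correlated at 0.051 to 0.079 and in LDN at 0.057 and 0.062, under the limit of 0.1 set for pairing. They still lay above libraries of different numbers (-0.061 to -0.011 in BMP4, -0.062 to 0.005 in LDN). Pairing is therefore neither shown nor excluded in these arms. The block gave 282 for BMP4, 220 for LDN and 2 for the interaction of BMP4 with RA. The replicate block shared across all groups gave 6 for BMP4 against RA in FOXA2-negative cells and 2 for the interaction of BMP4 with RA.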

Other observations

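In this part the list of 2-cell-stage genes and the tests on a few strongly changed genes, on copy number, on the Y chromosome and on 2 kinds of interaction splits were chosen only after the result was seen.

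Slc2a1, a glucose transporter gene, was lower in BMP4 than in RA in FOXA2-positive cells and higher in LDN than in RA in both fractions, and in RA it was higher in FOXA2-positive than in FOXA2-negative cells (log2 fold change 0.58, edgeR adjusted p = 0.0196, a call lost without any of 4 of the 6 libraries). The hypoxia list, which holds Slc2a1, was called in no contrast (smallest adjusted p 0.0625). Of 17 listed genes of the 2-cell-like state, a rare state of embryonic stem cell cultures, 14 were measured. All 14 had negative log2 fold changes, FOXA2-positive against FOXA2-negative, in each treatment. Only 6 were called lower in RA, 4 in BMP4 and 1 in LDN, with none called higher. No test of the list as a whole is reported here. In LDN FOXA2-negative cells the SD exceeded the mean for some but not all of the genes, such as Zscan4a (16 ± 26.3 CPM). Many of the listed genes belong to multi-copy families, so their counts are uncertain.

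Of the 32 lists, 20 were called in at least 1 contrast and 12 in none. The 12, with their smallest adjusted p over all contrasts, were Shh pathway targets and ventral progenitors (0.214), Hedgehog co-receptors (0.224), forebrain and midbrain (0.201), postmitotic neurons (0.152), node and notochord (0.133), mesoderm (0.184), cadherins (0.308), FGF response (0.0812), S phase (0.381), p53 targets (0.0625), immediate early and dissociation genes (0.111) and hypoxia (0.0625). Single members could still differ, such as Ptch1, Cdh2 and Tubb3 in RA.

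In FOXA2-positive cells the median fold change of chromosome 8 genes was negative in all 9 windows of 15 Mb in each treatment, and that of chromosome 6 genes positive in 10 of 10 windows in RA and BMP4 and 9 of 10 in LDN, the weakest being 60 to 75 Mb (17 genes; log2 0.01, 0.06 and -0.09). With the trends in GC content, exonic length and expression level removed, the smallest median shift of chromosome 6 or 8 over the 3 treatments was still 0.24 on the log2 scale, which argues against these as its source. A few strongly changed genes cannot move a median over so many genes. Without called genes at least 75.2% of the genes still pointed in the direction of their chromosome. With so few calls on these chromosomes that had to follow, so it adds no support. Unequal copy number and a regulatory difference between the fractions both stay open, because the count of autosomes with library medians that did not overlap between fractions in all 3 treatments (2 of 19, 6 and 8) restates the shift and cannot separate them. Loss of the Y chromosome from part of the FOXA2-positive cells stays open too: all 5 measured genes had negative log2 fold changes in each treatment, but none was called in LDN, and with errors of up to 2.14 the test for unequal folds (lowest chi-square p 0.193) had little power.

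Other splits of the same 6 libraries were fitted for comparisons of 3 against 3, where 10 splits are too few for a share under 0.05. In each case the real split was the 1 with as large a count: 212 genes for the RA sort (highest other 0), 164 for the BMP4 sort (1), 14 for BMP4 against RA in FOXA2-negative (0) and FOXA2-positive cells (1), 7 for LDN against RA (0) and 35 for BMP4 against LDN in FOXA2-negative cells (1). In RA, where numbers were taken to pair the libraries, the other 3 splits that part all 3 pairs gave 0. For the interaction of BMP4 with RA, 25 of 100 splits drawn from 200 gave at least the real count of 1. In 60 of the 100 unequal numbers of libraries were exchanged in the 2 fractions, so that the treatment difference itself enters the interaction, and these say nothing about chance. In the other 40, where a treatment difference shared by the fractions cancels, 4 gave at least the real count, the real split among them (highest other 1). A count of 1 is the smallest a call can give. These splits therefore cannot exclude chance for the count and say little about the gene called. The highest other count of all was 9, several times the real count, from 1 of the 60, where the treatment difference enters. That split kept the treatment groups of FOXA2-positive cells whole with their labels exchanged, and mixed those of FOXA2-negative cells. The same was true of 8 more splits, with counts of 0 to 2, and why 1 of them gave more was not tested.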
